A study of Rattus norvegicus with 28 samples.

How the data were processed

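The series holds 28 arrays with 2 channels each. Per the labels, channel 1 held RNA of an injected animal and channel 2 RNA of an uninjected control of the same region, each channel with its own Alexa dye, and the dyes were never swapped. Injected pups received 0.25% carrageenan in 0.9% saline, or saline, at 1 µl/g into the left hindpaw on postnatal day 3, were weaned on day 21 and kept until day 59. Per the labels' protocols, total RNA was extracted with TRIzol, 5 µg of each sample was reverse transcribed, and the dye was bound with a 3DNA kit (65 °C, 3 h) on custom oligonucleotide arrays for 205 genes. How spots were scanned, filtered, corrected for background and normalized is not given in the sources used here. Animals injected on another postnatal day and animals with adjuvant inflammation, which the series text mentions, were not analysed here.

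The values used were those of the deposited table, 1 log2 ratio per feature and array, as the authors made it. The table states neither log base, centring nor direction. Base 2 was inferred from the values, which ran from -13.245 to 10.459: as natural or decimal logs these would exceed what a 16-bit scanner can give. Injected over uninjected is the likely direction, since channel 1 was the injected animal throughout. Of the 378 pairs of arrays, 348 shared at least 15 measured features; across these features r was positive in 311 (median 0.266) and below -0.3 in 7, the lowest -0.51, over at most 54 features. With zeros kept, 1 pair was below -0.3 (-0.41 between PAG saline array 3 and RVM carrageenan array 2). Of the 7 pairs, 5 were between regions, 1 was between groups of a region and 1 was within a group, so opposing regions do not account for all of them. The direction was kept for every array because the labels state the same dyes throughout.

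Of 6384 values 3566 (55.9%) were exactly 0, while 0.001 and -0.001 occurred 9 and 14 times, so an exact 0 was taken as not measured. The number of arrays and measured features limits the precision; 3 features were 0 on every array and 2 were measured on every array. Array medians of the measured values lay between -0.061 and 0.083. Their span of 0.144 was below the limit of 0.5 set for centring, so values were used as deposited. By array number, the medians were 0.045, 0.011, -0.019, 0.056 and 0.083 in PAG carrageenan, -0.019, 0.015, -0.01, -0.016 and 0.037 in PAG saline, and -0.013, 0.02, 0.034, -0.053 and 0.0045 in RVM carrageenan. They were 0.0115, 0.008, -0.001 and 0.02 in RVM saline, 0.0605, 0.0395, 0.003, -0.0035 and 0.004 in left LDH, and -0.061, -0.019, 0.006 and 0.0035 in right LDH.

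Features were named from the platform annotation, with symbols updated through a rat RefSeq gene table (assembly GRCr8). Of 228 features 202 had 1 symbol, 26 had none and 0 had several; 191 matched the gene table and 11, Ntsr1 feature 158 among them, kept the annotation's name. The named features covered 156 genes, 30 of them with more than 1 feature. Features of 1 gene were kept separate and are given by number. No genome build is stated for the array, so no coordinates are given.

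Each comparison was fitted with limma (version 3.58.1, R 4.3.3; lmFit and eBayes, two-sided) on the arrays of its own groups, with no covariates. A feature entered when each group of the fit had at least 3 measured arrays. P-values were adjusted by Benjamini-Hochberg within each of 11 comparisons at a threshold of 0.05. A group against its uninjected controls was the group mean against 0 in the fit of its region; the spread of the controls enters only through the ratio. The interaction used PAG and RVM arrays in 1 fit, and the region test was a moderated F over 3 groups. Differences between groups in measured features and in array SD were tested by exact two-sided permutation. Intervals are 95% intervals from limma.

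Lists of genes were 23 in number, of which 14 had at least 3 features on the array and 6, housekeeping and glial markers among them, had none. They were tested with limma's camera on the moderated statistics with a preset correlation of 0.01 where at least 3 members were measured, which gave 75 tests over 9 comparisons, adjusted within each comparison. An estimated correlation (the mean residual correlation of the members, at least 0) was the alternative. Fry was run on the features measured on every array. It tests a list against no change, not against the other features. Only the glutamate receptors in the PAG comparisons had enough such features, so the fry p-values had no other list to adjust over. Named genes followed a rule: every feature that passed, up to 12 in each direction if more than 24 passed, the 10 with the smallest p where fewer than 10 passed, the measured opioid and tachykinin features in comparisons between injected groups, and list examples by p. The groups, comparisons, lists, rule for named genes and the first set of alternatives below were fixed before the data were examined.

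These alternatives were median centring, quantile normalization, features measured on every array, robust variance, all 6 groups in 1 fit, array weights, the replicate number as a block, an exact permutation test of each feature and leaving out each array. Chosen after seeing the data were zeros kept as 0, a minimum of 2 measured arrays, a minimum of 3 in the tested group alone, leaving out the 4 arrays with fewer than 40 measured features, leaving out PAG saline arrays 3 and 4, and the glutamate receptors without Grik3. The steps were tested on simulated data, with 20 tables per comparison. Values were drawn independently from normal distributions, with the real pattern of measured values and an SD per feature pooled over the groups. Correlation between features, array effects and a spread that differs between groups were not simulated. The rates that follow thus describe an easier case than the real data. A known log2 difference of 1, 2 or 4 was recovered in 25%, 57.5% and 92.5% of features for PAG carrageenan against saline (78 features), 27.5%, 57.5% and 93.8% for RVM (56 features), and 27.5%, 73.8% and 95% for LDH left against right (29 features). For PAG carrageenan against uninjected (78 features) these were 48.8%, 83.8% and 98.8%. In the same order of comparisons, 10 of 150, 12 of 155, 5 of 162 and 15 of 200 calls were false. Of 20 tables without a change, 0, 2, 0 and 0 held a call. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.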

Results

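Gene expression in pain-related regions of the central nervous system of male rats was measured on 28 custom oligonucleotide arrays, each hybridised with RNA of an injected animal and RNA of an uninjected control from the same region. Pups had been given carrageenan, a seaweed polysaccharide that inflames tissue, or saline into the left hindpaw on postnatal day 3, and were kept until day 59. The regions were labelled PAG (the usual abbreviation of the periaqueductal grey of the midbrain), RVM (the rostral ventromedial medulla of the brain stem) and LDH (the lumbar dorsal horn of the spinal cord). There were 5 arrays of PAG carrageenan, 5 of PAG saline, 5 of RVM carrageenan, 4 of RVM saline, 5 of the left LDH and 4 of the right LDH, both sides from carrageenan-injected animals. Each array gave 1 log2 ratio for each of 228 features, which covered receptors, transporters, neuropeptide precursors, neurotrophins and cytokines. Ratios are given as injected over uninjected, the likely direction, because the injected animal was channel 1 on every array; the deposited table does not state it. No label says that the arrays of a group came from separate animals, so p-values measure the spread between arrays, which may be technical.

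The number of features with a ratio was compared between groups. Of 6384 values, 3566 (55.9%) were exactly 0 and were taken as not measured. PAG carrageenan arrays measured 148.8 ± 36.9 features (SD, n = 5), against 80.8 ± 26.8 on PAG saline arrays (n = 5; exact permutation p = 0.0397). RVM carrageenan arrays measured 69.8 ± 39.8 features (n = 5), against 145.5 ± 38.9 on RVM saline arrays (n = 4; exact permutation p = 0.0476). The left LDH arrays measured 104.4 ± 38.7 (n = 5) and the right ones 54.25 ± 38.8 (n = 4; exact permutation p = 0.0873). Without the arrays that measured fewer than 40 features, a setting chosen after seeing the data, the RVM difference went from -75.7 to -48.8 (exact permutation p = 0.114). In RVM these were carrageenan arrays 2 and 4, left out for low values of the outcome itself in the lower group. The difference therefore had to shrink. The SD of the ratios within an array averaged 1.47 in PAG carrageenan and 0.97 in PAG saline (n = 5 each; exact permutation p = 0.0476), 1.30 and 1.59 in RVM (exact permutation p = 0.397), and 1.27 and 1.40 in left and right LDH (exact permutation p = 0.778). After Benjamini-Hochberg adjustment over these 6 permutation tests, the smallest value was 0.0952, so none held. Without the arrays that measured fewer than 40 features, the PAG difference in array SD had an exact permutation p of 0.0952 (unadjusted). In RVM, every one of the leave-one-out fits except that without saline array 1 raised the unadjusted p on measured features above 0.05.

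**Figure D1:**
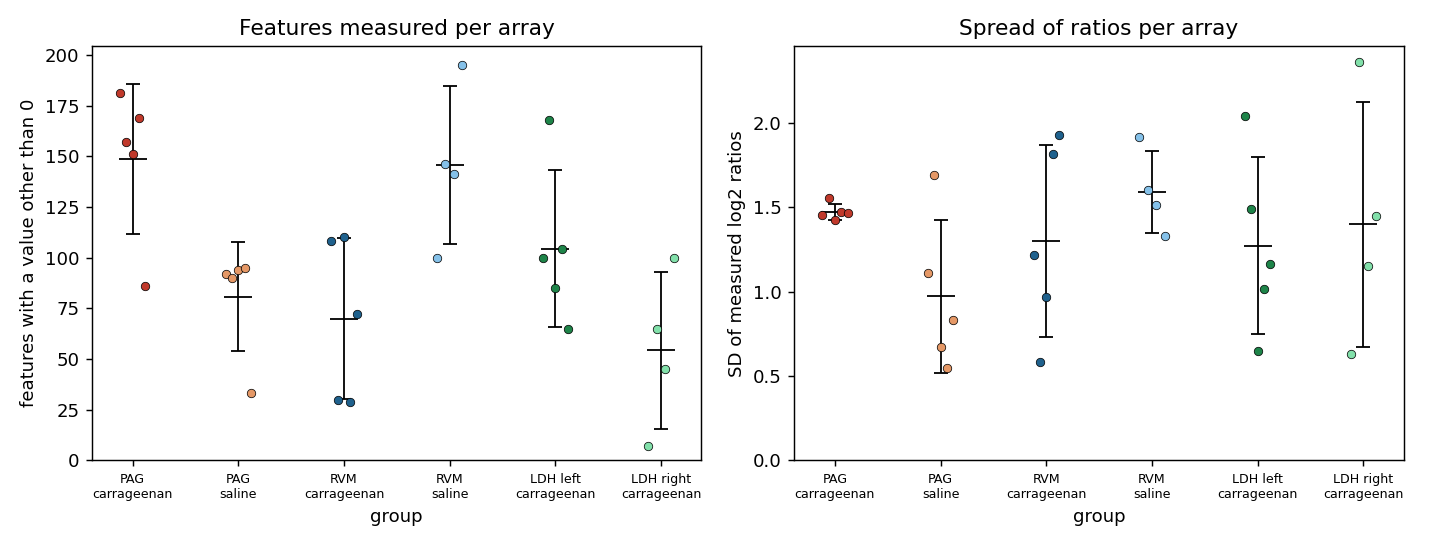
Features measured per array (left, number of features with a value other than 0) and SD of the measured log2 ratios per array (right) in the 6 groups. Points are arrays, long bars the group mean and whiskers 1 SD. PAG saline array 5 measured 33 features, against 90 to 95 on the other 4 arrays of its group.

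The first comparison asked which ratios differed between carrageenan and saline in PAG. The smallest p belonged to Gabbr1, a subunit of the metabotropic GABA-B receptor, whose feature 76 averaged -1.58 ± 0.83 after carrageenan (SD, n = 5, below 0 on 5 of 5 arrays) and 0.14 ± 0.90 after saline (n = 5). That difference was -1.71 (95% interval -2.87 to -0.56). The other Gabbr1 features tested, 36 and 37, given after their values were seen, differed by -0.066 and 0.45. Slc6a13, a GABA transporter, lay the other way, at 1.21 ± 0.72 (n = 4) against -0.26 ± 0.23 (n = 3). So did Htr4, a serotonin receptor, at 0.58 ± 0.50 (n = 5) against -0.28 ± 0.31 (n = 4). Hrh3, a histamine receptor, averaged -0.0068 ± 0.16 after carrageenan (n = 5) and 0.69 ± 0.50 after saline (n = 4). With limma, 0 of 78 features passed an adjusted p of 0.05, 10 had an unadjusted p below 0.05 (7 higher and 3 lower after carrageenan, with 3.9 expected by chance). The exact permutation test of each feature called 0, but says little here. The smallest p it allows is 0.00794, so fewer than 13 features could not have passed. The smallest adjusted p by limma was 0.333, shared by Gabbr1, Slc6a13, Htr4 and Hrh3, and Slc6a13 alone passed (adjusted p = 0.0442) when all 6 groups shared 1 limma fit.

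The other features with an unadjusted p below 0.05 were 4 named and 2 unnamed ones. Ntsr1, a neurotensin receptor, averaged 1.26 ± 1.18 against 0.01 ± 0.33 (n = 5 each), and Klk1b3, a kallikrein-family peptidase, 1.43 ± 0.89 (n = 4) against 0.07 ± 0.41 (n = 3). Tac1, the substance P precursor, averaged 0.70 ± 0.46 (n = 5) against -0.05 ± 0.50 (n = 4) on feature 55. Its second feature, 79, differed by 0.34 (95% interval -0.75 to 1.42). Ngfr, the low-affinity neurotrophin receptor, averaged 0.62 ± 0.77 against -0.22 ± 0.41 (n = 5 each). The unnamed features 62 and 181 differed by 0.53 and -0.29. None of these passed the adjusted threshold.

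Opioid and tachykinin genes, named in advance for their place in pain control, gave intervals that all included 0 except that of Tac1 feature 55. Pdyn, the dynorphin precursor, averaged 0.97 ± 0.58 after carrageenan (n = 4) and 0.49 ± 0.22 after saline (n = 5), a difference of 0.49 (95% interval -0.13 to 1.11) whose sign turned under quantile normalization (-0.33). Pomc, the beta-endorphin precursor, differed by 0.55 on feature 191 (95% interval -0.20 to 1.29). It differed by 1.09 on feature 198 (95% interval -0.73 to 2.91). Penk, the enkephalin precursor, differed by 0.81 on feature 194 (95% interval -1.09 to 2.72) and by -0.07 on feature 196 (95% interval -0.63 to 0.48). The tachykinin receptors Tacr2 and Tacr3 differed by 1.09 (95% interval -0.53 to 2.72) and -0.27 (95% interval -1.34 to 0.80).

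As groups, no list of genes separated carrageenan from saline in PAG by limma's camera test, which asks whether a list moves more than the other features (smallest adjusted p = 0.267 over 10 lists). Means were higher after carrageenan for 4 of 5 opioid features, 3 of 4 tachykinin features, 8 of 10 neuropeptide precursor features, 6 of 8 neuropeptide receptor features and 4 of 4 neurotrophin features. The same held for 4 of 6 serotonin features and 3 of 4 noradrenaline and dopamine features, whereas 7 of 9 GABA and glycine receptor features and 6 of 11 glutamate receptor features were lower. Among 5 cytokine and chemokine receptor features 3 were higher, with median and mean above 0 and the test directed down. Over all 78 features the median difference was 0.14, so a majority above 0 was not particular to these lists. Adjusted over the list alone, 0 features passed in any of the 10 lists.

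**Figure D2:**
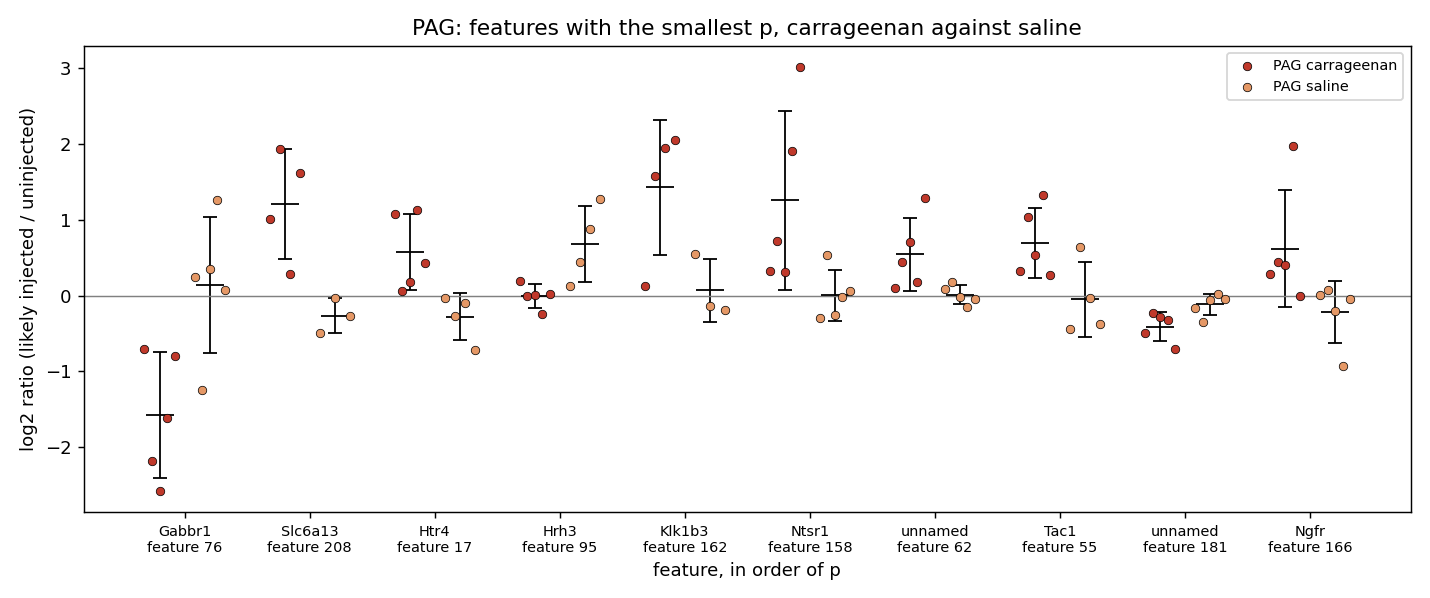
Log2 ratios (likely injected over uninjected) of the 10 features with the smallest p in PAG carrageenan against PAG saline, ordered by p. Points are arrays, long bars the group mean and whiskers 1 SD; Gabbr1 feature 76 lay below 0 on 5 of 5 carrageenan arrays and on 1 of 5 saline arrays, and none of the features passed the adjusted threshold.

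The same comparison was made in RVM, where no feature passed. Il11ra1, an interleukin 11 receptor subunit, averaged -0.13 ± 0.21 after carrageenan and 0.41 ± 0.29 after saline (n = 4 each). Sstr5, a somatostatin receptor, averaged -0.03 ± 0.30 and 1.06 ± 0.59 (n = 3 each). Tacr2 averaged 0.03 ± 0.16 against 0.62 ± 0.44, and Tac1 feature 55 -0.07 ± 0.17 against 1.22 ± 1.18 (n = 4 each). Gabbr1 feature 76 went the other way, at -0.26 ± 0.30 against -1.08 ± 0.50 (n = 4 each, a difference of 0.82 with a 95% interval of 0.16 to 1.48), and Gabbr1 feature 37 differed by -0.29. With limma, 0 of 56 features passed (smallest adjusted p = 0.465), 4 had an unadjusted p below 0.05 (1 higher and 3 lower, with 2.8 expected by chance). The exact permutation test of each feature called 0, with a smallest possible p of 0.00794 to 0.1 by feature, so fewer than 9 features could not have passed. Without RVM saline array 4, Adra2a feature 33, an adrenergic receptor, was called (adjusted p = 0.0266 by limma); with all arrays it averaged 0.035 ± 0.045 (n = 3) against 0.58 ± 0.42 (n = 4).

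Further features of this comparison had intervals that included 0. These were Ntf4, a neurotrophin (0.87, 95% interval -0.05 to 1.80), Grik3 feature 88, a kainate receptor subunit (-1.49, 95% interval -3.21 to 0.23), Htr4 (-0.59, 95% interval -1.29 to 0.10) and the unnamed feature 144 (0.86, 95% interval -0.12 to 1.84). Penk differed by -0.53 on feature 194 (95% interval -1.54 to 0.47) and by 0.46 on feature 196 (95% interval -0.61 to 1.53), and Tac1 feature 79 by -0.80 (95% interval -2.58 to 0.97). The 3 measured tachykinin features were all lower (median difference -0.80), but the list did not pass camera (adjusted p = 0.199). No other list did either: noradrenaline and dopamine features were lower in 3 of 3, neuropeptide precursors in 5 of 6, neuropeptide receptors in 4 of 6 and serotonin features in 4 of 6. Neurotrophin features were higher in 2 of 3 and glutamate receptors in 5 of 8, cytokine receptors were split at 2 of 4, and GABA and glycine receptors were lower in 4 of 5 and cytokines in 2 of 3. The median and the test differed in sign for GABA and glycine receptors, and the mean and the test for glutamate and for GABA and glycine receptors. Over all 56 features the median difference was -0.097, so a majority below 0 was not particular to a list. Adjusted over the list alone, 0 features passed.

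In LDH of carrageenan-injected animals the left side, that of the injected paw, was set against the right. Il11ra1 averaged 0.74 ± 1.03 (n = 4) against -0.28 ± 0.38 (n = 3), Il9r 0.36 ± 0.84 (n = 3) against -0.41 ± 0.39 (n = 4), Il13ra2 0.22 ± 0.58 (n = 4) against -0.42 ± 0.91 (n = 3), and the cytokine Il10 2.00 ± 2.48 against -0.11 ± 0.30 (n = 3 each). As a list, cytokine and chemokine receptors were higher on the left in 3 of 3 measured features (camera adjusted p = 0.0276), and the adjusted p was 0.139 with an estimated correlation between features. That call was also lost under quantile normalization (0.0891), with all 6 groups in 1 fit (0.131), with array weights (0.305), with zeros kept as 0 (0.271), with at least 2 measured arrays per group (0.895) and without LDH right array 1 (0.0689). With the replicate number as a block the call was kept (camera adjusted p = 0.0136), but not with an estimated correlation (0.0853). The labels state no such pairing. Without LDH left array 1, 3 or 4, or LDH right array 2, 3 or 4, fewer than 3 features were left and the list was not tested. No single feature passed: with limma, 0 of 29 had an adjusted p below 0.05 (smallest 0.854), and 0 had an unadjusted p below 0.05. The exact permutation test of each feature called 0, and with these numbers of arrays fewer than 5 features could not have passed it.

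The other LDH features gave wide intervals. Grin2b, an NMDA receptor subunit, differed by -0.36 (95% interval -0.93 to 0.21), Grin2d feature 171 by 0.51 (95% interval -0.77 to 1.79), and the unnamed features 221, 142, 144 and 199 by 0.46, -0.19, -0.25 and 0.30. Of the genes named in advance, Tac1 feature 55 differed by -0.54 (95% interval -2.47 to 1.39), Oprm1, the mu opioid receptor, by -0.36 (95% interval -2.24 to 1.51) and Penk feature 194 by 0.25 (95% interval -1.09 to 1.59). Glutamate receptors were lower on the left in 2 of 3 features, GABA and glycine receptors higher in 3 of 4, neuropeptide precursors higher in 2 of 3 (with mean and test below 0) and neuropeptide receptors lower in 3 of 4. The median difference over all 29 features was 0.18. None of these 4 lists passed (smallest adjusted p = 0.615), and 0 features passed adjusted over the list alone.

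Each injected group was then set against its uninjected controls, with the mean ratio tested against 0. The injected sample and the control each carried their own dye on every array, without a swap, so an effect of the dyes is not separated from that of the injection in what follows. In PAG carrageenan, 11 of 78 features passed by limma, of which 7 rose and 4 fell, and 26 had an unadjusted p below 0.05. The features that fell were Grik3 feature 88, at -4.99 ± 3.23 (SD, n = 5, adjusted p = 0.0224), Gabbr1 feature 76, at -1.58 ± 0.83 (n = 5, adjusted p = 0.0224), Grin2d feature 167, another NMDA receptor subunit, at -0.99 ± 0.50 (n = 5, adjusted p = 0.0224), and the unnamed feature 181, at -0.41 ± 0.19 (n = 5). Each lay below 0 on 5 of 5 arrays. The other features of these genes that were tested, given after their values were seen, did not pass with the main settings. Grin2d feature 171 averaged 0.039 ± 0.10 (n = 5, above 0 on 3 of 5 arrays), Gabbr1 feature 36 -0.36 ± 0.35 (n = 5) and Gabbr1 feature 37 0.85 ± 0.63 (n = 3, above 0 on 3 of 3). With at least 2 measured arrays per group, Gabbr1 feature 35 passed at 0.94 and Grik3 feature 89 at -3.12 (adjusted p = 0.0334 each by limma). That setting was chosen after seeing the data, and Gabbr1 feature 35 lay opposite to feature 76. Of the 7 that rose, Slc6a13 averaged 1.21 ± 0.72 (n = 4, adjusted p = 0.0342) and the serotonin transporter Slc6a4 0.88 ± 0.39 (n = 4, adjusted p = 0.0224). Pdyn averaged 0.97 ± 0.58 (n = 4, adjusted p = 0.0224), the neurotensin precursor Nts 0.57 ± 0.30 (feature 184, n = 5, adjusted p = 0.0227) and Ntsr1 1.26 ± 1.18 (n = 5, adjusted p = 0.049). Klk1b3 (1.43 ± 0.89, n = 4) and the unnamed feature 62 (0.54 ± 0.48, n = 5) completed the 11. All 7 lay above 0 on every array that measured them.

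These calls rested on few arrays. Leaving out PAG carrageenan array 1, 2, 3 or 4 left 3, 1, 6 and 4 features, and leaving out PAG saline array 1, 3 or 4 left 7, 6 and 6, since the saline arrays shape the variance estimate and the features tested. With zeros kept as 0, a choice made after seeing the data, 9 of 213 features passed, 1 higher and 8 lower. Of the 11, the 4 that fell and Nts were among them, and the other 6 that rose were not (adjusted p from 0.0599 to 0.0683). Over the features measured on every array, which leave out those that rose on 4 arrays, 9 of 22 passed, 3 higher and 6 lower. Under quantile normalization 0 features passed, with all 6 groups in 1 fit 7 did, and with every feature that PAG carrageenan alone measured on at least 3 arrays 2 of 155 did, namely Grin2d feature 167 and Oprd1 feature 54. Ntsr1 and the unnamed feature 62 also lost their calls with median centring (adjusted p = 0.0524 and 0.0647) and robust variance (0.0517 each). The same held with at least 2 measured arrays per group (0.0532 and 0.0552). In PAG saline 0 of 78 features passed by limma (smallest adjusted p = 0.0699) and 9 had an unadjusted p below 0.05. The difference between both PAG groups is the carrageenan against saline comparison above, in which 0 features passed. Grin2b feature 169 averaged -0.45 ± 0.20 in PAG saline (n = 5, below 0 on 5 of 5 arrays), and passed over the features measured on every array (adjusted p = 0.00751) and without PAG saline array 3 (adjusted p = 0.026).

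The other PAG saline features among the 10 with the smallest p did not pass with the settings used. Hrh3 averaged 0.69 ± 0.50 (n = 4) and passed when all 6 groups shared 1 fit (adjusted p = 0.0135). Pdyn averaged 0.49 ± 0.22 (n = 5), Slc6a4 0.48 ± 0.19 (n = 3) and Grin2d feature 167 -0.44 ± 0.29 (n = 5). Adora2a feature 24, an adenosine receptor, averaged 1.45 ± 1.52 (n = 4), Gad2, a GABA-synthesising enzyme, 0.26 ± 0.16 (n = 4), Il10ra, an interleukin 10 receptor subunit, -0.27 ± 0.32 (n = 5), and the unnamed features 144 and 199 -0.60 ± 0.72 (n = 4) and 1.19 ± 1.44 (n = 3). Under quantile normalization 4 features passed, which were Grik3 feature 88, Grin2b feature 169, Pdyn and the glutamate transporter Slc1a6.

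Glutamate receptors fell as a list in PAG carrageenan. Of 11 measured features 8 were lower than uninjected (median -0.13, mean -0.67; camera adjusted p = 0.00469). The adjusted p was 0.0028 with an estimated correlation, and limma's fry test, run on the features measured on every array, gave an adjusted p of 0.000372. Grik3 feature 88 and Grin2d feature 167 passed over all features tested and also adjusted over the list alone, while Grin2b feature 169 averaged -0.25 and Grm5, a metabotropic receptor, -1.59 without passing. Without the Grik3 features, a setting chosen after seeing the data, 7 of 10 were lower (adjusted p = 0.0477). In PAG saline 8 of 11 glutamate receptor features were lower too (camera adjusted p = 0.0731, and 0.0528 with an estimated correlation, again 0). Fry on the complete features gave a p of 0.0024 there. There 1 glutamate receptor feature passed adjusted over the list alone and 0 over all features tested, and without the Grik3 features the camera adjusted p was 0.223.

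No other list passed camera in either PAG group (smallest adjusted p = 0.351 in carrageenan and 0.663 in saline). In PAG carrageenan, features above 0 numbered 5 of 6 for serotonin, 4 of 4 for noradrenaline and dopamine, 5 of 5 for opioids, 3 of 4 for tachykinins, 9 of 10 for neuropeptide precursors, 7 of 8 for neuropeptide receptors, 4 of 4 for neurotrophins, 6 of 9 for GABA and glycine receptors and 2 of 5 for cytokine receptors. Over all 78 features the median was 0.19 in PAG carrageenan and 0.045 in PAG saline. A majority above 0 was therefore not particular to a list. In PAG carrageenan, adjusted over the list alone, 4 serotonin features passed against 1 over all features tested, and 3 neuropeptide precursors against 2. For noradrenaline and dopamine and for tachykinins this was 1 against 0, for opioids and for GABA and glycine receptors 1 against 1, and for neuropeptide receptors 0 against 1. For GABA and glycine receptors the median and the mean lay above 0 and the test pointed down, and for cytokine receptors the mean differed in sign from the median and the test. In PAG saline, neurotrophin features were below 0 in 4 of 4, tachykinins in 3 of 4 and neuropeptide precursors in 5 of 10, whereas GABA and glycine receptors were above 0 in 7 of 9, serotonin features in 4 of 6, noradrenaline and dopamine features in 3 of 4, neuropeptide receptors in 6 of 8, opioids in 3 of 5 and cytokine receptors in 3 of 5. There, mean, median and test did not share a sign for opioids, neuropeptide precursors and cytokine receptors.

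In RVM carrageenan only Grik3 feature 88 passed among 56 features by limma: it fell by 4.06 on the log2 scale (SD 1.14, n = 3, below 0 on 3 of 3 arrays, adjusted p = 0.0134), and 5 features had an unadjusted p below 0.05. It was no longer tested without RVM carrageenan array 1, 3 or 5, which left 0 calls, and with all 6 groups in 1 fit its adjusted p was 0.294. Htr2c, a serotonin receptor, averaged 0.93 ± 0.60 (n = 4), Gria2, an AMPA receptor subunit, -1.63 ± 0.58 (n = 3), and Vipr2, a receptor for vasoactive intestinal peptide, -0.35 ± 0.27 (n = 4). Penk averaged -0.90 ± 0.87 on feature 194 and 0.70 ± 0.94 on feature 196 (n = 3 each), so its features lay on opposite sides of 0. Hrh3 (0.17 ± 0.08, n = 5), Ntsr1 (0.44 ± 0.73, n = 4), the adrenergic receptor Adra2c (0.16 ± 0.22, n = 5) and Gad2 (0.56 ± 1.01, n = 3) were the remaining features among the 10 with the smallest p.

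In RVM saline 3 features fell by limma and 13 of 56 had an unadjusted p below 0.05. Gabbr1 feature 76 averaged -1.08 ± 0.50 (n = 4, adjusted p = 0.0373), Grik3 feature 88 -2.57 ± 0.92 (n = 4, adjusted p = 0.0373) and Vipr2 -0.68 ± 0.30 (n = 4, adjusted p = 0.0409), each below 0 on 4 of 4 arrays. Gabbr1 feature 37 averaged 0.36 ± 0.92 (n = 3, above 0 on 1 of 3 arrays) and did not pass. Leaving out RVM saline array 2 or 3 left 0 calls and leaving out array 4 gave 9, with Hrh3, Tacr2, Adra2a feature 33, Il11ra1, Htr4 and Htr2c added, while all 6 groups in 1 fit gave 0. Vipr2 also lost its call with quantile normalization (adjusted p = 0.215), robust variance (0.055), array weights (0.0805) and at least 2 measured arrays (0.0703). Gabbr1 feature 76 lost its call with quantile normalization too (adjusted p = 0.291 by limma). Grik3 feature 88 lost its call with zeros kept as 0 (adjusted p = 0.141 by limma), a choice made after seeing the data. The features that follow had means above 0 and did not pass: Hrh3 (0.45 ± 0.30, n = 4), Tacr2 (0.62 ± 0.44, n = 4), Sstr5 (1.06 ± 0.59, n = 3), Adra2a feature 33 (0.58 ± 0.42, n = 4), Il11ra1 (0.41 ± 0.29, n = 4), Tac1 feature 55 (1.22 ± 1.18, n = 4) and Htr4 (0.65 ± 0.59, n = 4).

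Glutamate receptors fell as a list in RVM saline, with 7 of 8 features lower (median -0.25, camera adjusted p = 0.0344), but not with an estimated correlation (adjusted p = 0.512). The call was also lost without the Grik3 features (adjusted p = 0.234), and without RVM saline array 3 or 4 or RVM carrageenan array 3 (adjusted p = 0.336, 0.188 and 0.38). Without RVM carrageenan array 1 or 5 the list was not tested. In RVM saline and in RVM carrageenan, 1 glutamate receptor feature passed adjusted over the list alone and 1 over all features tested. In RVM carrageenan 4 of 8 were lower (adjusted p = 0.251), with a median of 0.0049 against a mean of -0.67 and a test directed down. Tachykinins were above 0 in 3 of 3 features in RVM saline (adjusted p = 0.234; 2 passed adjusted over the list alone and 0 over all features tested) and in 2 of 3 in RVM carrageenan. The smallest adjusted p of the other lists was 0.308 in RVM saline and 0.704 in RVM carrageenan. In RVM saline and RVM carrageenan respectively, features above 0 numbered 4 and 5 of 6 for serotonin, 3 and 2 of 3 for noradrenaline and dopamine, 5 and 3 of 6 for neuropeptide precursors, 5 and 4 of 6 for neuropeptide receptors, 2 and 3 of 3 for neurotrophins, 2 and 2 of 3 for cytokines, 1 and 2 of 4 for cytokine receptors and 4 and 3 of 5 for GABA and glycine receptors. Over all 56 features the median was 0.19 in RVM saline and 0.053 in RVM carrageenan. A majority above 0 was therefore not particular to a list. In RVM saline, 3 neuropeptide receptor features passed adjusted over the list alone against 1 over all features tested, and 1 noradrenaline and dopamine feature against 0. Median, mean and test did not share a sign for GABA and glycine receptors and cytokine receptors in either group, for neurotrophins in RVM saline, and for tachykinins, neuropeptide precursors, neuropeptide receptors and cytokines in RVM carrageenan.

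**Figure D3:**
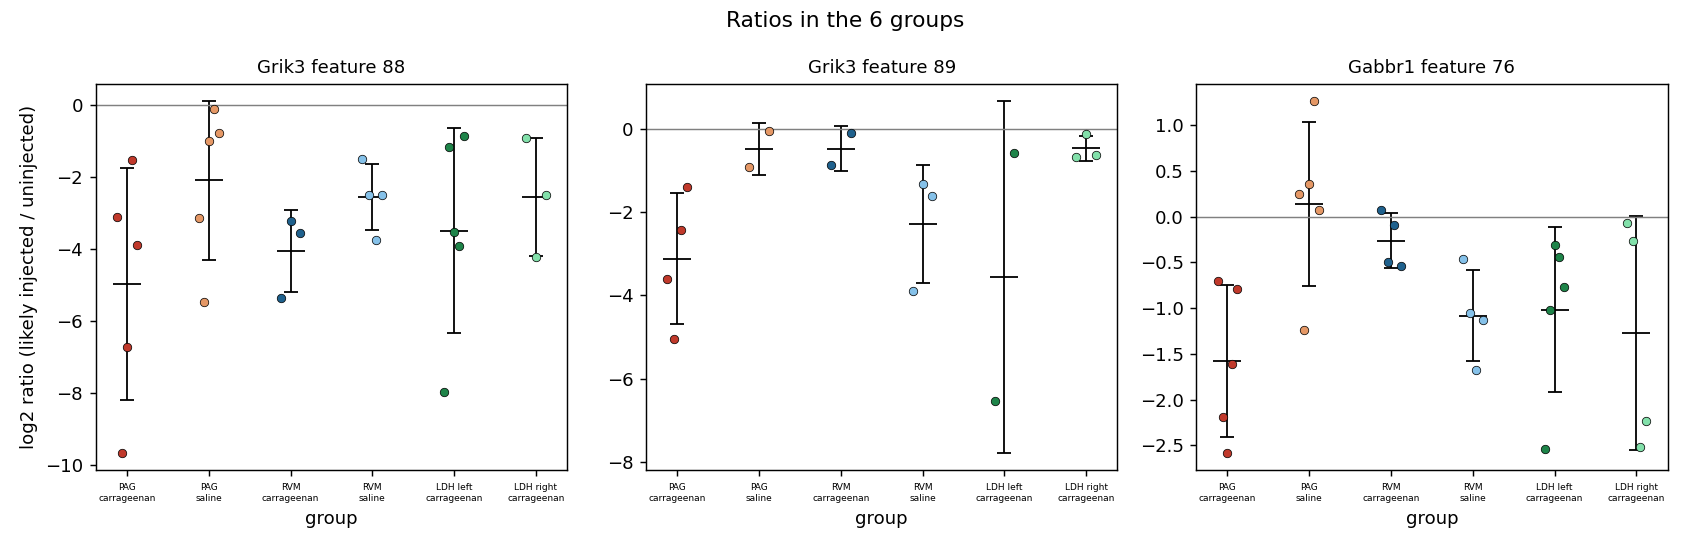
Log2 ratios (likely injected over uninjected) of both Grik3 features and of Gabbr1 feature 76 in the 6 groups. Points are arrays, long bars the group mean and whiskers 1 SD; Grik3 feature 88 lay below 0 on all 25 arrays that measured it.

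In LDH, 0 of 29 features passed by limma on either side. On the left 5 had an unadjusted p below 0.05, all below 0 on 5 of 5 arrays: Grik3 feature 88 at -3.50 ± 2.85, Grin2b at -0.38 ± 0.34, Oprm1 at -1.19 ± 1.26, Gabbr1 feature 76 at -1.01 ± 0.90 and the unnamed feature 144 at -0.35 ± 0.30 (n = 5 each; smallest adjusted p = 0.233). On the right 1 did, Gabbr1 feature 76 at -1.27 ± 1.28 (n = 4; adjusted p = 0.557), and Grik3 feature 88 averaged -2.56 ± 1.64 (n = 3). The left features with the next smallest p were Il10 (2.00 ± 2.48, n = 3), Gabrq, a GABA-A receptor subunit (0.40 ± 0.32, n = 5), Il11ra1 (0.74 ± 1.03, n = 4), Ntf4 (-0.50 ± 0.78, n = 4) and Sstr2 feature 213 (0.40 ± 0.73, n = 5). The right ones were Grin2d feature 171 (-0.996 ± 0.75, n = 3), Gabrq (0.50 ± 0.61, n = 4), Ngfr (1.14 ± 1.92, n = 3), Gabrr1 (-0.83 ± 1.35, n = 3), Tac1 feature 55 (0.96 ± 1.19, n = 3), Il9r (-0.41 ± 0.39, n = 4), Oprm1 (-0.83 ± 1.19, n = 3) and the unnamed feature 71 (-0.53 ± 0.86, n = 3). Glutamate receptors fell as a list on the left, 3 of 3 features lower (camera adjusted p = 0.0256), with an adjusted p of 0.274 with an estimated correlation and 0.0581 without LDH left array 2. It was not tested without LDH right array 2, 3 or 4, nor without Grik3 feature 88, which left 2 features. Of its features 1 passed adjusted over the list alone against 0 over all features tested. They were lower in 3 of 3 on the right without passing (adjusted p = 0.442). Over all 29 features the median ratio was 0.13 on the left and -0.085 on the right. No other list passed (smallest adjusted p = 0.414 on the left and 0.581 on the right): on the left and right, features above 0 numbered 2 and 2 of 4 for GABA and glycine receptors, 2 and 2 of 3 for neuropeptide precursors, 3 and 3 of 4 for neuropeptide receptors, whose mean differed in sign from median and test, and 3 and 0 of 3 for cytokine receptors.

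Whether carrageenan against saline differed between PAG and RVM was tested as an interaction. Gabbr1 feature 76 had the largest difference of differences, -2.53 (95% interval -3.91 to -1.16; adjusted p = 0.0633), since carrageenan lay below saline in PAG and above it in RVM. For Gabbr1 feature 37 it was 0.74. Htr4 and Tac1 feature 55 lay the opposite way, at 1.45 (95% interval 0.56 to 2.33; adjusted p = 0.0806) and 2.03 (95% interval 0.68 to 3.38; adjusted p = 0.096). With limma, 0 of 48 features passed and 3 had an unadjusted p below 0.05. Gabbr1 feature 76 passed with array weights (adjusted p = 0.0144) and without PAG carrageenan array 1 or 5, PAG saline array 2 or RVM saline array 1 (adjusted p = 0.0343, 0.0393, 0.00659 and 0.0417), the last of which also called Htr4 (adjusted p = 0.0417). The next features, Tacr2 (1.69), Il11ra1 (0.70), Gabrq (0.97), Ngfr (1.07), Adrb3 (1.17), Polr2m (-0.64) and Ntsr1 (1.21), had an adjusted p of 0.515.

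**Figure D4:**
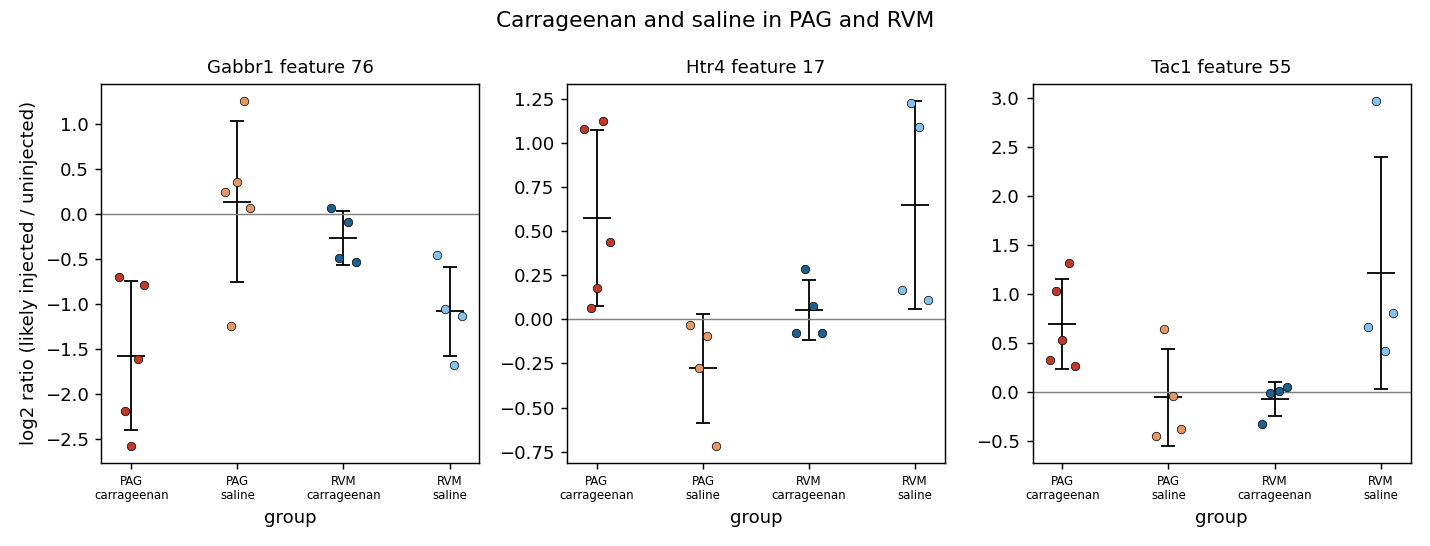
Log2 ratios (likely injected over uninjected) of Gabbr1 feature 76, Htr4 and Tac1 feature 55 in PAG and RVM after carrageenan and saline. Points are arrays, long bars the group mean and whiskers 1 SD; group means of Gabbr1 were -1.58 and 0.14 in PAG and -0.26 and -1.08 in RVM, and the interaction did not pass (adjusted p = 0.0633).

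Ratios of carrageenan over uninjected were last compared between PAG, RVM and left LDH. Slc1a6, a glutamate transporter, averaged -0.53 ± 0.53 in PAG (n = 5), -0.17 ± 0.14 in RVM (n = 3) and 0.30 ± 0.42 in LDH (n = 4). Gabbr1 feature 76 averaged -1.58 ± 0.83 (n = 5), -0.26 ± 0.30 (n = 4) and -1.01 ± 0.90 (n = 5). Penk feature 196 averaged 0.14 ± 0.17 (n = 4), 0.70 ± 0.94 (n = 3) and -0.26 ± 0.38 (n = 5). Adra2a feature 33 averaged 0.09 ± 0.29 (n = 5), 0.035 ± 0.045 (n = 3) and 0.93 ± 0.98 (n = 3), and Gabrd, a GABA-A receptor subunit, -1.21 ± 1.35 (n = 5), -0.53 ± 0.90 (n = 3) and 0.26 ± 0.86 (n = 5). By limma's moderated F test, 0 of 51 features passed (smallest adjusted p = 0.744) and 1, Slc1a6, had an unadjusted p below 0.05. The unnamed features 50 and 144, Polr2m, Gabre and Gabrq made up the rest of the 10 with the smallest p.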

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

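The test of features that only some PAG arrays measured and the sign patterns below were set out before their results were seen; the other tests here were chosen after.

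By Dixon's test, single arrays stood far from the rest of their group in 17 of 115 groups of a named feature. Chance would give about 1 in 20 (5.75) if values were normal and groups independent, but several of the 17 share an array. In left LDH, array 1 held Gabrd at 1.77, Grin2b at -0.99 and the unnamed feature 199 at 1.14. In PAG carrageenan, array 5 held Adrb3 at 2.50, and array 4 held Il11ra1 at 1.46, Ngfr at 1.97 and Tacr2 at 3.71. In PAG saline, array 4 held Il10ra at -0.83 and Ngfr at -0.93, array 2 held Tacr3 at 0.69, and array 5 held Grin2d feature 167 at 0.051. In RVM carrageenan, array 5 held Ngfr at 1.05. In RVM saline, array 4 held Adra2a feature 33 at -0.042, and array 2 held Adrb3 at 1.72, Tac1 feature 55 at 2.97, Gabrq at 2.41 and the unnamed feature 144 at -1.64. PAG saline array 5 measured 33 features, against 90 to 95 on the other 4 arrays.

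Htr4 lay below 0 on every PAG saline array that measured it and above 0 on every RVM saline array (means -0.28 and 0.65, a difference of -0.93, n = 4 each). It was the 1 such split among 90 combinations of a named feature with an untested pair of groups. Chance is therefore not excluded, and the difference was not tested.

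Grik3 feature 88 lay below 0 on all 25 arrays that measured it (median -3.15, from -9.67 to -0.11), in every group. The second Grik3 feature, 89, was below 0 on 16 of 16 arrays (median -1.12). Of 84 features measured on at least 15 arrays, 2 lay below 0 on all of them and 0 above. A constant dye bias of feature 88 alone would not place feature 89 below 0, so feature 89 argues against that narrower explanation. A dye bias of both features may account for the pattern, and so may the injection or anything else that sets injected from uninjected animals. A permutation test of differences between the 6 groups in feature 88 gave p = 0.443, which leaves both open. They cannot be told apart, because every array carries the same dyes in the same channels and both carrageenan and saline were injected.

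The wider spread on PAG carrageenan arrays was also there over the 22 features measured on all PAG arrays, with a mean array SD of 1.37 ± 0.54 against 0.67 ± 0.34 (ratio 2.05, n = 5 each, exact permutation p = 0.0317). The PAG difference in array SD over all measured features had p = 0.0952 by exact permutation without the arrays that measured fewer than 40. The ratio over shared features argues against features that only some arrays measured as the whole explanation, and without Grik3 the ratio was 1.81 (exact permutation p = 0.0397). An effect of carrageenan in any region could not be settled, since the ratio of carrageenan over saline in RVM was 0.818 (exact permutation p = 0.397). A difference in how the PAG arrays were hybridised or scanned, and a carrageenan effect in PAG alone, stay open as untested.

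In the 5 comparisons between injected groups or regions the real count was 0, which all 100 of 100 splits reach by construction, so regrouping the arrays says nothing about chance there; the highest of the other splits had 1 in each. For the comparisons against uninjected with calls, the sign patterns of the arrays were too few for a share below 0.05. In PAG carrageenan, 1 of 16 patterns reached the real 11 features (highest other 0), in RVM carrageenan 4 of 16 reached the real 1 (highest other 1), and in RVM saline 1 of 8 reached the real 3 (highest other 0).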

How the results depend on the processing

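Alternatives other than leaving out an array left 1108 values of named features on the same side of the threshold and in the same direction, 54 lost the call, 7 gained it and 4 turned sign. Only features called with the main settings could lose a call: 11 in PAG carrageenan, 1 in RVM carrageenan and 3 in RVM saline. Most of the 1108 values had no call to lose, so that number does not show that the calls were stable. Centring on housekeeping genes was not run, because 0 such genes were on the array. Causes were not tested unless given. Signal over background was not in the table used here, and the features tested follow from which values were measured.

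Counts of features called moved as follows, with smaller changes of a count above 0 left out. PAG carrageenan against saline gave 1 with all 6 groups in 1 fit (Slc6a13) and 1 with zeros kept (Oprd1), against 0. RVM carrageenan against saline gave 4 with zeros kept (Htr5b, Hrh1, Grin3a, Pomc feature 192), 1 with at least 2 measured arrays (Grin3a) and 0 to 1 leaving out an array (1 without RVM saline array 4), against 0. PAG carrageenan against uninjected gave 0 under quantile normalization, 7 with all 6 groups in 1 fit, 2 with the minimum set on its own group (155 features tested) and 1 to 9 leaving out an array, against 11. The counts were 3, 1, 6 and 4 without PAG carrageenan arrays 1 to 4, and 7, 6 and 6 without PAG saline arrays 1, 3 and 4. PAG saline gave 4 under quantile normalization, 1 over features measured on every array, 1 with all 6 groups in 1 fit, and 0 to 1 leaving out an array (1 without PAG saline array 3), against 0. RVM carrageenan gave 0 over features measured on every array, with all 6 groups in 1 fit and with zeros kept, and 0 to 1 leaving out an array (0 without RVM carrageenan array 1, 3 or 5, when Grik3 had too few arrays to be tested), against 1. RVM saline gave 1 under quantile normalization, 0 over features measured on every array, 0 with all 6 groups in 1 fit, 9 with zeros kept, 6 with the minimum set on its own group, and 0 to 9 leaving out an array (0 without RVM saline array 2 or 3, 9 without array 4), against 3. The interaction gave 1 with array weights (Gabbr1), 6 with zeros kept, and 0 to 2 leaving out an array (2 without RVM saline array 1; 1 without PAG carrageenan array 1 or 5 or PAG saline array 2), against 0. Against 4 with the main settings, 1 list was called with an estimated correlation (glutamate receptors in PAG carrageenan, where the estimate was 0). By fry 2 were called, and 2 over features measured on every array. These last 2 settings could test only the glutamate receptors in the PAG comparisons, so their counts cannot be set against 4. With Grik3 left out 2 were called (72 lists tested against 75, since the glutamate list of LDH had too few features). Leaving out an array gave 2 to 5 (2 without LDH right array 2, 3 or 4, when the cytokine receptor and glutamate lists of LDH had too few features to be tested).

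Values that turned sign were Pdyn in PAG carrageenan against saline under quantile normalization (-0.33), Penk feature 196 with array weights (0.011) and leaving out an array (-0.25 to 0.087), Tacr3 (-0.61 to 0.014) and Tac1 feature 79 (-0.0060 to 0.65) leaving out an array, Grik3 feature 88 in RVM with zeros kept (0.13, an average with values not measured), and in LDH Oprm1 (-0.63 to 0.17), Penk feature 194 (-0.020 to 0.66) and the difference in array SD (-0.383 to 0.194) leaving out an array.

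With the replicate number as a block, 0 features passed in each of the 4 comparisons so fitted (76, 34, 29 and 30 features tested), and Oprm1 in LDH turned to 0.36. Same-numbered arrays correlated from -0.26 to 0.45 in PAG, -0.06 to 0.24 in RVM and -0.78 to 0.22 in LDH, and the same number was the best match for 1 of 5 in PAG, 3 of 4 in RVM and 1 of 4 in LDH; the labels state no pairing. Leaving out any array but PAG saline 2 raised the permutation p of the PAG difference in array SD above 0.05, as did leaving out any but RVM saline 1 for the measured features in RVM. Without the 4 arrays that measured fewer than 40 features, PAG carrageenan against uninjected gave 9 calls, all among the 11, and without PAG saline arrays 3 and 4 the comparison with carrageenan gave 0 of 25; both settings, as the zeros kept, the other minimums and the lists without Grik3, were chosen after seeing the data.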

Other observations

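The features in this paragraph were chosen after their values were seen, and several were left out of the comparisons because the other group of their region measured them on fewer than 3 arrays. Oprd1, the delta opioid receptor, averaged -2.32 ± 0.64 in PAG carrageenan (SD, n = 5, below 0 on 5 of 5 arrays) and was measured on 0 of the 5 PAG saline arrays. It averaged -2.11 ± 1.31 in RVM saline (n = 3), and the 2 left LDH arrays that measured it gave -2.35 and -2.21, whereas single arrays of RVM carrageenan and right LDH gave 0.28 and 3.04. Grin3a, an NMDA receptor subunit, averaged -4.37 ± 0.75 in RVM saline (n = 4, below 0 on 4 of 4 arrays), and the 2 RVM carrageenan arrays gave -0.47 and 0.21. The metabotropic glutamate receptors Grm4 (feature 150) and Grm8 averaged -2.90 (from -4.31 to -1.29, n = 4) and -2.09 ± 0.35 (n = 3) in RVM saline, whereas Grm4 feature 150 averaged 0.48 ± 0.65 in PAG carrageenan (n = 5). The 2 RVM carrageenan arrays gave Grm4 feature 150 at -2.06 and -1.16, and single left and right LDH arrays at -1.06 and -4.72. For Grm8, 2 left LDH arrays gave -2.75 and -1.43, and PAG carrageenan averaged -0.60 ± 1.48 (n = 3). Low values of these features were thus not particular to RVM saline. The second Grm4 feature, 149, had a median of -0.066 over all arrays that measured it (below 0 on 11 of 19). In RVM saline the histamine receptor Hrh1 averaged 1.77 ± 0.51 (n = 4). Hrh1 lay above 0 on every array that measured it, in other groups too. It averaged 3.21 ± 2.97 in PAG carrageenan (n = 3), and 2 left LDH arrays gave 1.81 and 1.83. With the minimum set on the tested group alone, limma gave adjusted p of 0.0377 for Oprd1 in PAG carrageenan and of 0.00305, 0.0428, 0.0485 and 0.0428 for Grin3a, Grm4, Grm8 and Hrh1 in RVM saline.

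The share of values measured is given by class, without a test. Over all 228 features, arrays averaged 148.8 measured features in PAG carrageenan, 80.8 in PAG saline, 69.8 in RVM carrageenan and 145.5 in RVM saline. A gap between these groups that runs the same way in a class is therefore not particular to that class. Cytokine and chemokine features had a value on 27.4% of feature-array combinations, from 11.7% in PAG saline to 47.5% in PAG carrageenan, and neurotrophins and their receptors on 65.3%. Both features of the noradrenaline transporter Slc6a2, the 2 catecholamine neuron marker features on the array, had a value on 90% of combinations in PAG carrageenan and 10% in PAG saline, and on 30% and 50% in RVM carrageenan and saline. For the 2 serotonin neuron marker features, Slc6a4 and Htr1a, this was 50% in both PAG groups, 60% and 62.5% in RVM carrageenan and saline, and 0 in both LDH groups. The other classes were measured on 33.2% (cytokine receptors) to 58.9% (tachykinins) of combinations.

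PAG saline arrays 3 and 4 correlated with each other at r = 0.705 over 90 shared features, and array 3 also correlated with RVM saline array 1 (r = 0.637 over 71 features); these r are across features, which are not independent replicates.

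Whether features of 1 gene report 1 change was tested after the Penk and Tac1 features had been seen to differ. Over 23 pairs of features from 14 genes, the median correlation across arrays was 0.112, against 0.0346 for pairs of different genes, a difference of 0.0771 (one-sided permutation p = 0.195, 10000 permutations). Single pairs, not tested one by one, ranged from -0.64 for Grm4 to 0.59 for Grik3, and the 4 pairs with Gabbr1 feature 76 were all negative (-0.15, -0.14, -0.22 and -0.37 with features 35, 36, 37 and 220). This leaves open whether the features of 1 gene measure a shared transcript.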
